A study of Mus musculus with 4 samples.

How the data were processed

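RNA-seq was made from mouse E14 embryonic stem cells, a pluripotent line grown on gelatin with serum and LIF. Cells had received 1000 ng of a pSuper puro plasmid expressing an shRNA against MERVL, which the labels call MuERVL, or a random shRNA. Per the labels' protocols, puromycin at 1 µg/ml was added 24 h after transfection and kept for 4 days, and total RNA went into a randomly primed mRNA-seq library kit. Each group had 2 libraries, and groups and replicate numbers were taken from the sample titles. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

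Per the submitters' processing notes, Trim Galore and HISAT2 were used and the genome build was mm10; versions and the counting program are not given in the sources used here, nor whether counting used strand. The authors deposited a table of estimated counts for 45773 features, of which 43496 were Ensembl genes and 2277 were single genomic copies named MERVL-int, the internal part of this endogenous retrovirus, or MT2_Mm, its long terminal repeat. Between 19.1% and 20.8% of the estimated counts in a library were not whole, as when reads that map to several copies are shared out, so the values of near-identical genes and copies are uncertain. Estimated counts were rounded to whole numbers before any count test. The second table the authors deposited holds a normalized score for each library and 17823 features, which were exactly the features with an estimated count above 5 in at least 2 libraries. How those scores were made is not given in the sources used here. On 7758 features with an estimated count above 200 in every library, the change from estimated count to score, beyond a shift per library, was a single factor that held 99.996% of the remaining variance. Its loadings were 0.754 and -0.652 in random shRNA replicates 1 and 2, and -0.0730 and -0.0285 in MERVL shRNA replicates 1 and 2. Gene names matched 42329 of the Ensembl identifiers, and positions came from GENCODE annotation of GRCm38, the assembly also called mm10. All columns of both tables were mapped to a sample.

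Totals were 15496921 and 11628887 estimated counts in random shRNA replicates 1 and 2, and 16067854 and 14570056 in MERVL shRNA replicates 1 and 2. The 10 most abundant features took 5.83% to 6.89% of a library. Intervals on shares of counts are 95% Wilson intervals and cover counting error only. All 13 protein-coding mitochondrial genes were listed at 0 in each library, so that list could not be tested.

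Genes and MERVL copies were tested together with the edgeR quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) after TMM scaling and filterByExpr, which left 15735 genes and 618 copies. The fit compared MERVL shRNA with random shRNA without a replicate term, tests were 2-sided, and p-values were adjusted by Benjamini-Hochberg over all features tested, with a threshold of 0.05. Standard errors were derived from the F statistic. CPM values are TMM-scaled. Gaps between the random shRNA libraries in a gene list are medians on log2(CPM + 1), which shrinks gaps of genes at low CPM. MERVL totals over all copies, and over the classes I, L, L_I and L_I_L that the copy names carry, were tested in a further edgeR fit together with the genes. Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 1 and a preset correlation of 0.01. Adjustment was over the 29 lists that had at least 5 measured members. Camera with an estimated correlation and fry were alternatives, where fry means its directional test unless the mixed test is named. The scores were tested with limma on log2(score + 1) for features with a mean of at least 1, and fold changes from them are on that scale. Other alternatives were other scalings, filters and dispersion priors, DESeq2 1.42.0, limma-voom, a replicate term, and leaving out each library.

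The tests, 30 gene lists, the rule for named genes and the alternatives, other than those named as chosen later, were fixed before the data were examined. The rule took genes with an adjusted p under 0.05, a mean of at least 1 CPM, both MERVL shRNA libraries on the same side of both random shRNA libraries and a symbol that is not a placeholder, up to 12 per direction. If under 5 genes passed, it added the 10 genes with the next smallest p, described as not having passed. It also took up to 4 members with the smallest p of each list described, and Zscan4c, Zscan4d, Zfp352, Tcstv3, Pou5f1, Sox2, Nanog, Zfp42, Dnmt3b, Trim28 and Kdm1a in any case. The tests were checked on simulated counts with the means and library sizes of these libraries, trended dispersion and 200 changed genes. There, edgeR recovered 78.8% of genes changed 4-fold, 40.3% of those changed 2-fold and 10.4% of those changed 1.5-fold, with 3 unchanged features called among 16061 tested. Both simulated groups had the same spread, whereas the real random shRNA pair was further apart (Pearson r 0.963) than the MERVL shRNA pair (0.989). These shares may therefore not hold for the real libraries. Camera called a simulated list of 40 genes shifted by 1 on the log2 scale (adjusted p = 2.23e-29) and 0 of 20 unchanged lists. It missed the shifted list with an estimated correlation (adjusted p = 0.115 with an estimated correlation). Simulated genes varied independently, so this check does not cover false calls of lists whose members move together. Estimated correlations of the lists in these libraries ran from -0.055 to 0.79. They were below the preset 0.01 for germline genes (-0.027), p53 targets (-0.032) and unfolded protein response genes (-0.032). Calls of those lists that were lost with an estimated correlation were therefore not lost through members moving together.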

Results

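The series asked how the transcriptome of E14 embryonic stem cells differs after shRNA against MERVL, an endogenous retrovirus that is transcribed in the 2-cell embryo and in a small, fluctuating share of embryonic stem cells. RNA from 2 random shRNA and 2 MERVL shRNA libraries was compared, with 11628887 to 16067854 estimated counts per library. The MERVL shRNA libraries had a Pearson r of 0.989 across features on log2 CPM, and the random shRNA libraries one of 0.963; features are not independent replicates. The first principal component held 66.7% of the variance. On it random shRNA replicates 1 and 2 lay at -67.1 and -1.04, and MERVL shRNA replicates 1 and 2 at 22.5 and 45.6. Random shRNA replicate 2 had a Pearson r of 0.980 and 0.976 with MERVL shRNA replicates 1 and 2, above that with random shRNA replicate 1. The chi-square of counts divided by its degrees of freedom was 6.37 for the MERVL shRNA pair and 35.1 for the random shRNA pair, a check for duplicate files of a single library, which would lie near 1; it says nothing more on how separate samples compare.

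RNA of the targeted element was lower in both MERVL shRNA libraries than in both random shRNA libraries, but the random shRNA libraries themselves differed 3.25-fold. Summed over all 2277 copies, MERVL stood at 4662 and 1434 CPM in random shRNA replicates 1 and 2, and at 1163 and 573.8 CPM in MERVL shRNA replicates 1 and 2. The group means were 3048 ± 2283 (SD, n = 2) and 868.5 ± 417 CPM (SD, n = 2). The log2 fold change was -1.83 ± 0.56 (SE), which did not pass the main edgeR test (adjusted p = 0.285). Nor did it pass with DESeq2 (adjusted p = 0.564) or limma-voom (adjusted p = 0.327). Other scalings, a CPM filter or a robust prior in edgeR gave adjusted p-values from 0.282 to 0.319. It passed in edgeR with no filter (-1.81 ± 0.20, adjusted p = 8.99e-17) and with a replicate block (-1.68 ± 0.23, adjusted p = 0.00106). Those SEs draw on a spread pooled over features, whereas MERVL itself differed 3.25-fold and 2.03-fold within the groups. The block pairs libraries by replicate number, and the labels do not say what same-numbered libraries share. Between same-numbered libraries, MERVL was 4.01-fold (replicate 1) and 2.50-fold (replicate 2) higher with random shRNA. As a share of all estimated counts MERVL took 0.472% (Wilson interval 0.468% to 0.475%) and 0.147% (0.145% to 0.149%) in the random shRNA libraries, against 0.115% (0.114% to 0.117%) and 0.0555% (0.0543% to 0.0567%) in the MERVL shRNA libraries. Copies of class L_I_L carried 88.7% of MERVL counts in random shRNA replicate 1, and their sum had a log2 fold change of -1.88 ± 0.57 (adjusted p = 0.285). The sums of classes L, L_I and I had log2 fold changes of -1.60, -1.55 and -0.95, with adjusted p-values of 0.270, 0.340 and 0.357. In class L_I random shRNA replicate 2 lay below MERVL shRNA replicate 1 (22.6 and 23.1 CPM), and in class I just above it (26.9 and 26.4 CPM). Of the 618 single copies tested, 503 were lower in both MERVL shRNA libraries than in both random shRNA libraries (81.4%, where chance gives 16.7% for independent copies). None passed the main edgeR test, while 461 had an unadjusted p under 0.05, and DESeq2 called 54 copies lower and limma-voom 0. The count in edgeR depended on the setting: it called 556 copies lower with no filter, 376 with a replicate block, 742 without random shRNA replicate 2, 38 without random shRNA replicate 1 and 0 without either MERVL shRNA library, and 0 higher each time. Without random shRNA replicate 1 the log2 fold change of the total was -0.73 ± 0.16 (adjusted p = 0.000275), but this SE is pooled over features, whereas MERVL itself differed 2.03-fold between the MERVL shRNA libraries and random shRNA replicate 2 was 1.23-fold above MERVL shRNA replicate 1. It passed as well without random shRNA replicate 2 (-2.44, adjusted p = 1.81e-56) and without MERVL shRNA replicate 1 (-2.42, adjusted p = 0.00916), but not without MERVL shRNA replicate 2 (-1.41, adjusted p = 0.356).

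**Figure D1:**
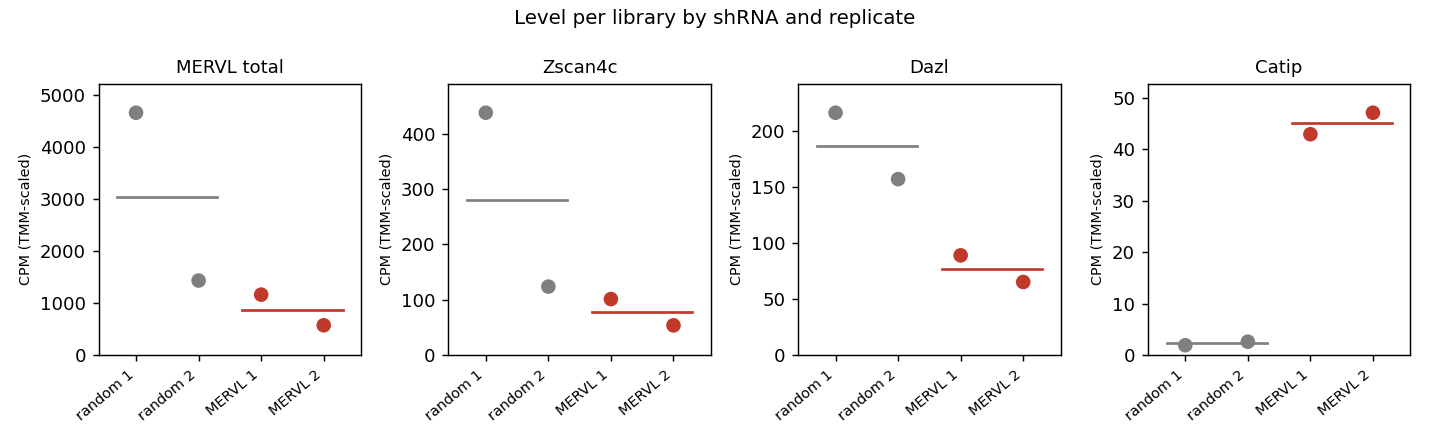
CPM (TMM-scaled, linear axis from 0) of the MERVL total, Zscan4c, Dazl and Catip in each of the 4 libraries; points are libraries and lines are group means (n = 2 each). Random shRNA replicate 1 was highest for MERVL (4662 CPM) and Zscan4c (438.3 CPM), whereas Catip was near 2 CPM in both random shRNA libraries and at 42.9 and 47.1 CPM in the MERVL shRNA libraries.

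Among genes, Catip, which encodes a ciliogenesis-associated protein, rose from 2.26 ± 0.485 CPM (SD, n = 2) to 45.0 ± 2.95 CPM (SD, n = 2), a log2 fold change of 4.33 ± 0.22 (SE; edgeR adjusted p = 0.00923). It lies on chromosome 1, positions 74362108 to 74369321 of GRCm38, on the plus strand. Catip was the single gene called out of 15735, with 1 higher and 0 lower. At an unadjusted p under 0.05 edgeR gave 766 genes higher and 999 lower, DESeq2 called 65 higher and 103 lower at its adjusted threshold, and limma-voom called 0 (Catip adjusted p = 0.0569). Genes for which both MERVL shRNA libraries lay on the same side of both random shRNA libraries numbered 3615 higher and 3440 lower, 44.8% of those tested where chance gives 33.3% on average. Genes vary together, so they are not independent trials, and this share alone does not show an effect of the shRNA. The call count depended on the setting: edgeR called 270 genes higher and 467 lower with no filter, 110 and 252 with a replicate block, 1144 and 1191 without random shRNA replicate 1, and 2557 and 2243 without random shRNA replicate 2, the lone library being assumed to vary like the other group. Without MERVL shRNA replicate 1 or 2, it called 2 genes higher and 0 lower each time.

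The 10 genes next in order of p did not pass, and each had both MERVL shRNA libraries outside the random shRNA values. Hmga2, a chromatin architectural protein of early embryos, had a log2 fold change of 1.95 ± 0.17 (adjusted p = 0.141), and its mean was 7.94 CPM with random shRNA and 30.6 CPM with MERVL shRNA. Stmn3, a regulator of microtubules, was at 2.26 ± 0.23, Atp2a3, a calcium pump of the endoplasmic reticulum, at 1.30 ± 0.14, and Slc11a1, a metal ion transporter of phagosomes, at 4.17 ± 0.45. On the other side, the cyclin-dependent kinase inhibitor Cdkn1c stood at -2.02 ± 0.22, with 21.2 CPM under random shRNA and 5.22 CPM under MERVL shRNA. The surface glycoprotein Thy1 was at -1.73 ± 0.22, the ubiquitin ligase Rnf11 at -1.42 ± 0.16, the metalloreductase Steap3 at -1.37 ± 0.18, the aminoacyl-tRNA synthetase complex protein Eef1e1 at -1.20 ± 0.14 and Serinc1 at -1.10 ± 0.13. Apart from Hmga2, the adjusted p-values of these genes ran from 0.161 for Stmn3 to 0.211 for Steap3. Slc11a1 lies downstream of Catip on the same strand, with 5873 bp between them.

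**Figure D2:**
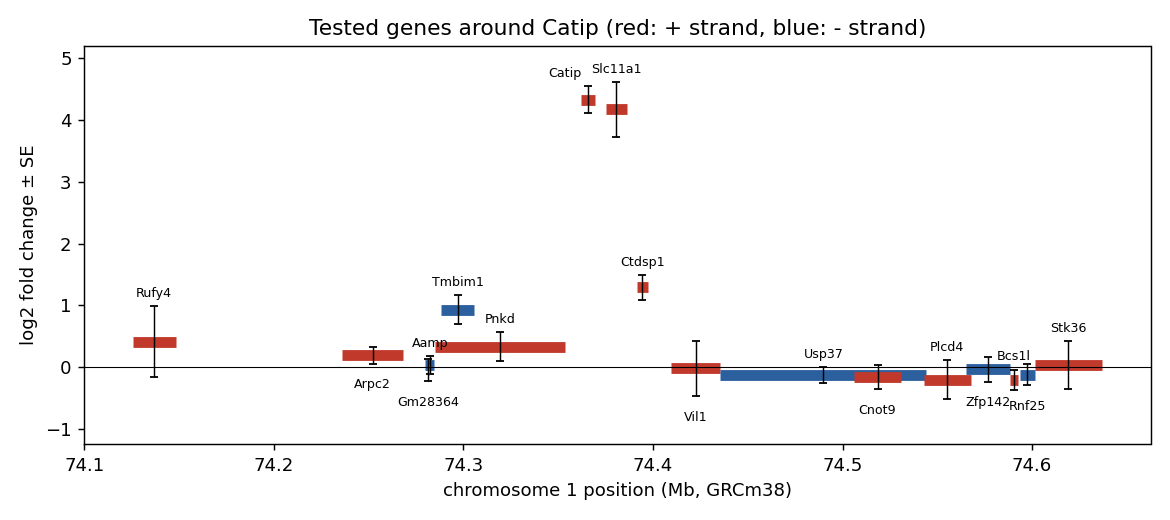
Log2 fold change (MERVL shRNA over random shRNA, y axis, error bars ± SE, n = 2 per group) of tested genes drawn at their positions on chromosome 1 (x axis, Mb, GRCm38). Catip and Slc11a1 stand at 4.33 and 4.17, Ctdsp1 and Tmbim1 at 1.29 and 0.93.

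Genes of the 2-cell embryo were lower as a group. Of 45 measured members of that list, 44 had a negative log2 fold change and the median was -1.91, with 38 lower in both MERVL shRNA libraries than in both random shRNA libraries. None passed over all genes tested in edgeR (38 had an unadjusted p under 0.05), and adjusted over the list alone 34 fell and 0 rose. Members moved together (estimated correlation 0.79), so these counts are not of independent genes. Adjustment over a list alone, here and below, makes no correction across the lists. Camera called the list lower (adjusted p = 2.58e-14), a call lost with an estimated correlation (adjusted p = 0.848 with an estimated correlation) and in fry (adjusted p = 0.541). Zscan4c, a telomere and genome stability factor expressed in 2-cell-like cells, was at 281.1 ± 222 CPM (SD, n = 2) with random shRNA and 77.6 ± 33.6 CPM (SD, n = 2) with MERVL shRNA, a log2 fold change of -1.86 ± 0.59. The means of Zscan4d were 203.6 and 50.8 CPM. Log2 fold changes were -2.30 for Zfp352, -2.25 for Tcstv3 and -5.56 for Tcstv1, the last with 0.126 and 0.284 CPM in the MERVL shRNA libraries. Gm13119, Gm13078 and Ubtfl1 had -1.31, -2.23 and -2.53. Many of these genes belong to families of near-identical copies, so the value of a single member is uncertain. Random shRNA replicate 1 was also above replicate 2 in this list, by a median of 1.57 on the log2 scale, and without it the list median was -0.80 (adjusted p = 1.25e-06).

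Germline genes were lower in both MERVL shRNA libraries with less dependence on that library. The median over 28 measured members was -0.68, 24 were negative, and 21 were lower in both MERVL shRNA libraries than in both random shRNA libraries. None passed over all genes in edgeR (16 had an unadjusted p under 0.05), and adjusted over the list alone 12 fell and 0 rose. Camera called the list lower (adjusted p = 1.06e-08) and fry did too (adjusted p = 0.0407), and the camera call was lost with an estimated correlation (adjusted p = 0.583 with an estimated correlation). Dazl, an RNA-binding protein of germ cells, went from 186.8 ± 41.9 CPM (SD, n = 2) to 77.2 ± 16.8 CPM (SD, n = 2), a log2 fold change of -1.28 ± 0.22. Syce1, of the synaptonemal complex, had -0.91 ± 0.18, Piwil2, of the piRNA pathway, -1.15 ± 0.25, and the bromodomain protein Brdt -1.76 ± 0.46. The list median stayed between -0.80 and -0.56 with any library left out, and random shRNA replicate 1 was above replicate 2 by a median of 0.15.

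Naive pluripotency genes were slightly higher. The median over 21 members was 0.26, 19 were positive, and adjusted over the list alone 4 rose and 0 fell, with 0 passing over all genes in edgeR and 7 at an unadjusted p under 0.05. Camera called the list higher (adjusted p = 0.00255), a call lost with an estimated correlation (adjusted p = 0.848 with an estimated correlation), in fry (adjusted p = 0.541) and without random shRNA replicate 2 (adjusted p = 0.138). In this list random shRNA replicate 1 was above replicate 2 by a median of 0.39 on the log2 scale, more than the change between groups, and the list median lay between 0.17 and 0.44 with a library left out. The nuclear receptor Nr0b1 had a log2 fold change of 1.07 ± 0.25, the DNA demethylase Tet2 0.77 ± 0.20, Fgf4 0.61 ± 0.14 and Klf5 0.55 ± 0.15. In the core pluripotency list of 18 genes the median was -0.03 and camera made no call (adjusted p = 0.537); adjusted over the list alone, Sall1 rose (0.97 ± 0.15) and Dnmt3l fell (-0.75 ± 0.14). Log2 fold changes were 0.23 ± 0.16 for Pou5f1, 0.20 ± 0.17 for Sox2, 0.04 ± 0.24 for Nanog, 0.20 ± 0.17 for Zfp42 and -0.21 ± 0.15 for Dnmt3b, none past the edgeR threshold.

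Ribosomal protein genes were higher by a median of 0.26, with 85 of 90 positive, 0 passing over all genes in edgeR, 4 at an unadjusted p under 0.05, and 0 passing when adjusted over the list alone. Camera called this list higher (adjusted p = 8.63e-08), which was lost with an estimated correlation (adjusted p = 0.848 with an estimated correlation), in fry (adjusted p = 0.641) and without random shRNA replicate 1 (median 0.09, adjusted p = 0.0801). Random shRNA replicate 1 was below replicate 2 in this list by a median of 0.43 on the log2 scale. Rps21, Rpl29 and Rps23 had log2 fold changes of 0.60, 0.52 and 0.45. The list was taken by name pattern, and Rpl6l in it (0.50) is annotated as a processed pseudogene.

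Targets of p53 had a median of -0.19 over 22 genes, with 16 negative, 0 passing over all genes in edgeR and 6 at an unadjusted p under 0.05. Adjusted over the list alone, 4 fell: Trp53inp1 (-0.96 ± 0.17), Pmaip1 (-0.72 ± 0.13), Eda2r (-0.59 ± 0.15) and Btg2 (-0.52 ± 0.14), which act in cell death or growth arrest. Camera called this list lower (adjusted p = 0.0338), as did fry (adjusted p = 0.0407), and the camera call was lost with an estimated correlation (adjusted p = 0.848 with an estimated correlation) and with any library left out (adjusted p from 0.0801 to 0.367). It was also lost with no filter (adjusted p = 0.0983) and with a replicate block (adjusted p = 0.150). Unfolded protein response genes had a median of -0.29 over 17 genes, and 15 were negative. Camera called this list lower (adjusted p = 0.0338), a call lost with an estimated correlation (adjusted p = 0.848 with an estimated correlation), in fry (adjusted p = 0.541), and without random shRNA replicate 1 (median -0.06, adjusted p = 0.416), MERVL shRNA replicate 1 (adjusted p = 0.298) or MERVL shRNA replicate 2 (adjusted p = 0.119). It was also lost with no filter (adjusted p = 0.105) and with a replicate block (adjusted p = 0.0948). Between the random shRNA libraries, replicate 1 was above replicate 2 by a median of 0.24 in this list and below it by 0.02 in the p53 list. Adjusted over the list alone, Sec61b of the translocon fell (-0.75 ± 0.13), and Sdf2l1, Dnajb9 and Edem1 had -0.64, -0.79 and -0.32.

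**Figure D3:**
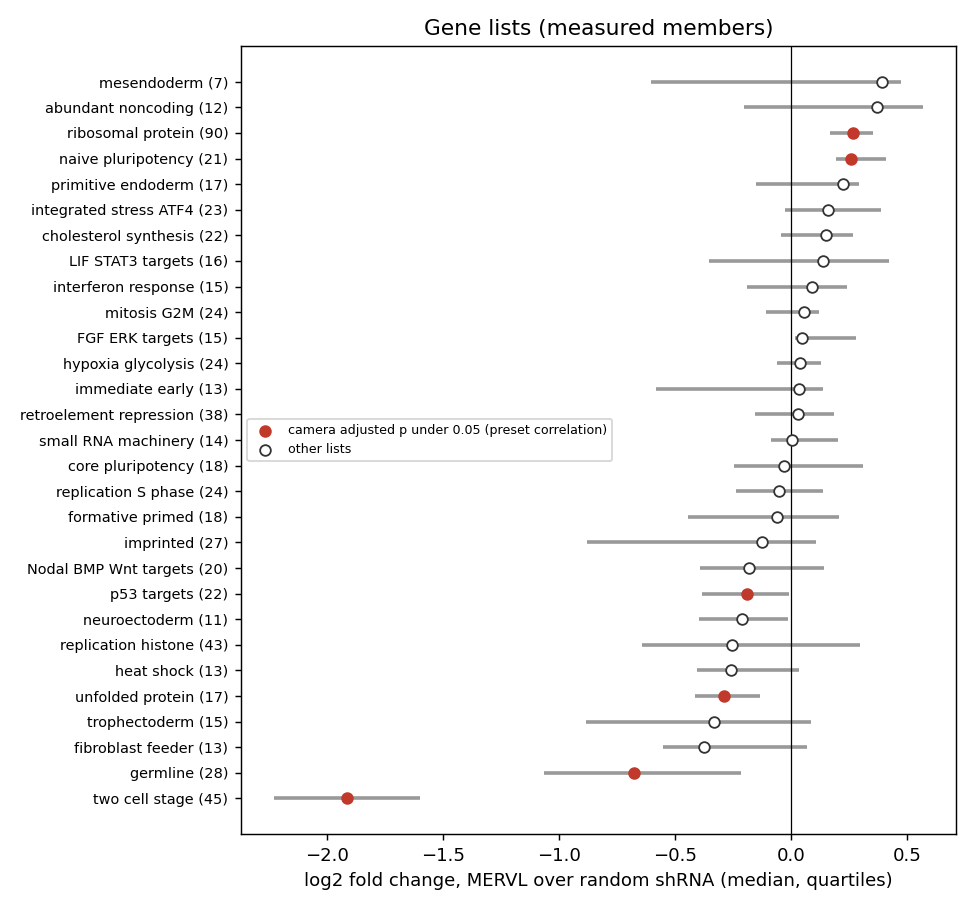
Median (points) and quartiles (lines) of log2 fold change, MERVL shRNA over random shRNA (x axis), over the measured members of 29 gene lists (y axis, number of members in parentheses). Filled points are the 6 lists with a camera adjusted p under 0.05 at the preset correlation; the 2-cell-stage list lies at -1.91 and the germline list at -0.68.

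With all 4 libraries, none of the other 23 lists tested passed camera, at the preset or an estimated correlation. The mixed test of fry, which takes changes in either direction together, passed 10 of the 29 lists (smallest adjusted p = 0.0113). These included the core pluripotency, trophectoderm, neuroectoderm, LIF-STAT3, imprinted and feeder lists. Imprinted genes had a median of -0.12 over 27 genes (adjusted p = 0.0709), and adjusted over the list alone Cdkn1c and Phlda2 (-0.88 ± 0.17), both maternally expressed growth restrictors, fell; Plagl1 and Nnat had -1.60 and -0.87. Trophectoderm genes had a median of -0.33 over 15 genes (adjusted p = 0.150), with -1.03 for Esx1, -1.99 for Gata2, -1.14 for Tfap2a and -1.23 for Ascl2, and 0 passing when adjusted over the list alone. Feeder or fibroblast genes, which could reveal other cells, had a median of -0.38 over 13 genes (adjusted p = 0.276), and adjusted over the list alone Thy1 fell. That median was -0.04 without random shRNA replicate 2, and between -0.39 and -0.32 without any other library. Retroelement repressors had a median of 0.03 over 38 genes (adjusted p = 0.631), and 0 passed when adjusted over the list alone. In that group log2 fold changes were -0.51 for Ezh2, 0.44 for Hdac2, -0.39 for Suz12, -0.80 for Zfp809, -0.33 ± 0.26 for Trim28 and 0.10 ± 0.14 for Kdm1a. Small RNA machinery had a median of 0.01 over 14 genes (adjusted p = 0.527).

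Lineage and signalling lists also had no camera call with all 4 libraries. Medians were 0.39 for mesendoderm, where Bmp4 rose when adjusted over the list alone (0.97 ± 0.17), and -0.21 for neuroectoderm, where Sox1 rose (1.62 ± 0.29) and Nes fell (-0.99 ± 0.25) when adjusted over the list alone. They were -0.06 for formative and primed genes, 0.22 for primitive endoderm, 0.05 for FGF-ERK targets, -0.18 for Nodal, BMP and Wnt targets and 0.14 for LIF-STAT3 targets. With a library left out, the neuroectoderm median ran from -0.37 to -0.08. That of Nodal, BMP and Wnt targets ran from -0.25 to -0.06, and that of LIF-STAT3 targets from 0.02 to 0.16. Stress and metabolic lists had medians of 0.16 for the ATF4 response, -0.26 for heat shock, 0.04 for hypoxia and glycolysis, 0.15 for cholesterol synthesis, 0.03 for immediate early genes and 0.09 for interferon response. Cell cycle and noncoding lists had medians of -0.05 for S-phase replication, 0.06 for mitosis, -0.26 for replication histones and 0.37 for abundant noncoding RNAs. The adjusted p-values of camera for these lists ran from 0.150 to 0.882, and apart from Bmp4, Sox1 and Nes 0 members passed when adjusted over the list alone. Median and mean differed in sign for mesendoderm (mean -0.12), immediate early genes (mean -0.20), retroelement repressors (mean -0.02) and core pluripotency (mean 0.01), and camera gave the direction of the mean for the second and the last. The mesendoderm median, over 7 genes, was negative with any library left out (-0.20 to -0.10), with no filter (-0.45), with the CPM filter (-0.07) and in the deposited scores (-0.01), so it gave no direction. The sign of the median also turned with at least 1 library left out for core pluripotency, formative and primed, primitive endoderm, retroelement repressor, small RNA, interferon, heat shock, hypoxia, cholesterol, immediate early, S-phase, mitosis, replication histone and abundant noncoding lists. Some of the 23 lists were called with a library left out, and hypoxia and glycolysis in opposite directions: lower without random shRNA replicate 1 (median -0.27, adjusted p = 0.00283) and higher without random shRNA replicate 2 (median 0.66, adjusted p = 1.90e-06). Without random shRNA replicate 1, trophectoderm genes were also called lower (median -0.78, adjusted p = 0.00283) and FGF-ERK targets higher (0.29, adjusted p = 0.0115). Without random shRNA replicate 2, cholesterol synthesis (0.44, adjusted p = 0.000240) and the ATF4 response (0.39, adjusted p = 0.0358) were called higher, and heat shock (-0.42, adjusted p = 0.00841), immediate early (-0.34, adjusted p = 0.0444) and replication histone genes (-0.44, adjusted p = 0.0418) lower. Without MERVL shRNA replicate 1, the ATF4 response was called higher (0.30, adjusted p = 0.0487) and imprinted genes lower (-0.44, adjusted p = 0.0487), and without MERVL shRNA replicate 2, abundant noncoding RNAs higher (0.69, adjusted p = 0.0329).

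In the deposited scores, limma called 2337 genes higher and 2402 lower of 17078, 27.7% of those tested, and 179 MERVL copies lower and 1 higher. Without either random shRNA library it called 0 genes in both directions, and without a MERVL shRNA library 5774 to 6477 higher and 5931 to 6737 lower. The same limma test on the estimated counts of the same features, scaled to a common total, called 1 gene higher and 0 lower, with 1842 at an unadjusted p under 0.05. Of the 4565 called genes that were also tested with edgeR, 4562 had the same sign of log2 fold change there, in the same libraries. The factor between estimated counts and scores had mean loadings of only 0.051 (random shRNA) and -0.051 (MERVL shRNA). It thus left the group differences nearly as they were, and the shared signs are no separate support for the calls. The random shRNA libraries had a Pearson r of 0.999 in the scores and 0.963 in log2 CPM. The factor taken out between estimated counts and scores mainly separated these libraries. That part of their spread therefore does not enter the limma tests on scores. Summed over the copies in that table, MERVL had a log2 fold change of -1.56 ± 0.43 and did not pass (adjusted p = 0.0713). Catip was at 4.20 ± 0.23 (adjusted p = 0.0244).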

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

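Settings run on the deposited scores without a library, on their estimated counts with the same limma test, and on the MERVL total other than with RLE or library size scaling were chosen after the data were seen, as were the agreement settings. The count of 1 gene higher, 0 lower and 1 changed at least 2-fold was the same with RLE, library size or upper quartile scaling, a CPM filter and a robust prior, and the first 2 at an adjusted p under 0.01. They became 270, 467 and 413 with no filter, 65, 103 and 101 with DESeq2, and 0, 0 and 0 with limma-voom. In the deposited scores they were 2337, 2402 and 715, with pseudocount 0.5 they were 2327, 2378 and 725, and with no filter on scores they were 2337, 2402 and 715. With a library left out the ranges were 2 to 2557, 0 to 2243 and 2 to 1214. The labels do not say what same-numbered libraries share. The deviations of same-numbered libraries correlated across features at 0.25, and a replicate block gave 110, 252 and 272 genes. The log2 fold change of the MERVL total went from -1.83 to -1.81 (adjusted p = 8.99e-17) with no filter, to -1.68 (adjusted p = 0.00106) with the replicate block, and to between -2.44 and -0.73 with a library left out, and was past the threshold in 3 of those 4. Over its alternatives with all 4 libraries the adjusted p ran from 8.99e-17 with no filter to 0.564 with DESeq2. The 2-cell-stage list median of -1.91 missed the threshold with an estimated correlation (adjusted p = 0.848) and in fry (adjusted p = 0.541) and lay between -2.52 and -0.80 with a library left out. Lists called numbered 6, with 0 at an estimated correlation, 2 in fry, 4 with no filter and 4 with the replicate block (p53 targets and unfolded protein response lost in both), and 5 to 10 with a library left out; camera uses no count model, so DESeq2, limma-voom and the robust prior were not run on it. The hypoxia list was called at -0.27 without random shRNA replicate 1, against its sign over all libraries, and in the other direction at 0.66 without random shRNA replicate 2, the ends of its range with a library left out; the immediate early list was likewise called at -0.34 without random shRNA replicate 2, in a range up to -0.080. In the scores, genes higher and lower were 0 to 6477 and 0 to 6737 with a library left out (0 and 0 without either random shRNA library), and 1 and 0 in the same limma test on estimated counts; the random shRNA libraries had a Pearson r of 0.999 there. Of 2126 values of 133 named genes, 632 gained a call, 1 lost it (Catip in limma-voom) and 0 reversed with a call. A further 7 changed sign with no call, 5 of them without random shRNA replicate 1. Leaving out a library changes from which pair the spread, pooled over features, is estimated; other causes were not tested.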

Other observations

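The tests below were chosen after the result was seen, except the random draws of neighbouring pairs; the limma test on estimated counts was added after the data were seen, with its bound set before its own result. The random shRNA libraries differed from each other in several gene groups beyond the 2-cell-stage list, which is described here as a difference between those libraries. Hypoxia and glycolysis genes were lower in random shRNA replicate 1 than in replicate 2 by a median of 0.92 on the log2 scale (log2(CPM + 1)), with 23 of 24 genes lower, and cholesterol synthesis genes were lower by 0.59, with 20 of 22 lower. Both medians lay below all 10000 random lists of the same size matched on mean expression. Egln3, an oxygen-sensing hydroxylase, stood at 7.08 and 46.9 CPM in random shRNA replicates 1 and 2, and at 37.7 and 46.3 CPM in the MERVL shRNA libraries, and Pdk1 at 169.5, 332.9, 291.5 and 314.4 CPM. Heat shock genes were higher in replicate 1 by 0.54, at the 99.98th percentile, and replication histone genes by 0.35, above all random lists.

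MERVL RNA and 2-cell-stage genes were lower together. Across the 4 libraries MERVL was 10.6, 11.6, 11.5 and 10.7 times Zscan4c, and the log2 ratio of MERVL to the summed list differed between groups by -0.016 (SD within groups 0.18), which argues against an shRNA acting on MERVL RNA alone. A state shared by MERVL and these genes that varies between cultures whatever the shRNA is a candidate explanation. Replicate 1 of random shRNA exceeded replicate 2 by 1.7 in MERVL (log2 CPM) and 1.57 in the list median (log2(CPM + 1)), a difference of 0.13. The added 1 shrinks gaps of genes at low CPM, so this difference is approximate. Whether random shRNA replicate 1 is the whole cause cannot be told apart from an effect of the shRNA: without it the log2 fold change was -0.73 ± 0.16, less than the gap between the random shRNA libraries, a bound that replaced 3 SE after this value was seen; that SE is pooled over features, and MERVL differed 2.03-fold within the MERVL shRNA pair. An effect of MERVL on the whole group of genes stays open as well and was not tested.

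The deposited scores and the estimated counts gave very different numbers of calls. The same limma test called 4739 genes in the scores and 1 in the estimated counts of the same features. The calls thus depended on the step from estimated counts to scores. On features with high counts, that step removed 1 factor beyond a shift per library. That factor correlated across features with the difference between the random shRNA libraries at -0.996, and GC content and gene length held 7.30% of its variance, which argues against them as its source. What the factor stands for stays open.

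Catip, Slc11a1, Ctdsp1 and Tmbim1, the last inside Pnkd on the other strand, are consecutive tested genes by start position on chromosome 1 and were each higher in both MERVL shRNA libraries. Among the 100 higher genes with the smallest p there were 6 neighbouring pairs, as in a share of 0.0002 of 10000 random draws; 2 of the pairs lay here and 4 elsewhere, some of them paralogs or overlapping genes, so this bound did not test the locus. A share of 0.1367 of the draws had at least 2 pairs, so chance cannot be told apart here, although Catip, Slc11a1 and Ctdsp1 made a run of 3, a measure picked after the run was seen, which a share of 0.005 of the draws matched. A gain that takes in most tested genes within 1 Mb is argued against by the other 33 there, with a median of -0.092. The CPM gained per kb was at least 2.15 times as high for Slc11a1 as for Catip, which argues against read-through of whole Catip transcripts. Counts per gene cannot decide on transcripts that hold only a part of Catip. A gain of these genes alone or an activation confined to this locus, such as a plasmid insertion or an effect of the shRNA there, may remain and was not tested.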
